A study of Mus musculus with 6 samples.

How the data were processed

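Total RNA of sorted KSL and Lin+ bone marrow cells was purified and amplified linearly, then labelled with biotin and hybridised, per the labels, to 1 Affymetrix array per pool, 6 arrays in all. KSL cells were sorted by flow cytometry with the same gates for every pool, and Lin+ cells by magnetic beads from the same mice. The deposited values are probe-set intensities, which the authors had scaled to a similar level on every array. The software and the scaling method are not given in the sources used here. That the intensities are on a linear scale was inferred from the values: they were positive, right-skewed and reached 22774.7 to 24208.3 on the 6 arrays, with 591 to 679 values per array at exactly 1. The arrays had similar medians but different quantiles, so they had not been quantile normalized. Values close to the top of the scale can be compressed. The pool sizes of the control mice are not given in the sources used here.

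The table held 45037 probe sets. Of these 34945 mapped to 1 gene in the probe annotation, 932 to several and 9160 to none, and the last 2 kinds were left out. Symbols were updated through the NCBI gene table, except for 204 gene identifiers absent from it, which kept the older symbol. Intensities were raised to a floor at the 20th percentile of all values (17.14) and set on the log2 scale, with no further normalization. Values under 45.9 are called near the floor and differences whose lower side holds one are lower bounds, also where given as log2, as are those with higher values over 10000, a reading chosen after the data were seen. For each of 18193 genes the probe set with the highest mean over the 6 arrays was used. Genes with a mean under the 40th percentile of all probe-set means (an intensity of 45.9) were left out, which left 12348 genes. The number of arrays limits the precision, with 2 residual degrees of freedom in each main fit. Fits without an array or pool, or on 1 cell type alone, have fewer, so a call lost there need not depend on what was left out.

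Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment at 0.05. KSL cells were compared with Lin+ cells over 3 pairs with the genotype as a block. Arthritic and control pools were compared within each cell type, and between cell types as an interaction, in 1 fit of the 4 groups. In that fit the spread comes from the 2 control pools of each cell type, so that strain counts as error, and the lone arthritic array is assumed to vary like the controls. Since arthritis coincides with the KRNxG7 genotype, genes at least 2-fold above or below both controls, with the higher side at or above the median of all values (77.6), were also counted without a test. The same count with KRN, then B6xG7, as the pool that stands apart served as background. Simulated data with 50 changed genes at each fold of 1.5, 2, 4 and 8 were tested in the same design. The simulated values had no floor, and only 50 of 12348 genes changed at each fold. The adjusted threshold was therefore stricter than where many genes differ, as in KSL against Lin+ cells, with 6421 of 12348 genes called. For that comparison the simulated shares below are no estimate of the real ones. For KSL against Lin+ cells 60% of 4-fold and 82% of 8-fold changes were called, for arthritic KSL cells 22% and 58%, and for arthritic Lin+ cells 32% and 60%. No unchanged gene was called, and of the 2-fold changes 14%, 0% and 2% were called.

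Gene lists of 23 kinds were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except those named as later. They were stem cell, lymphoid priming, myeloid priming, megakaryocyte-erythroid priming, neutrophil granule and maturation, late erythroid, B cell, plasma cell, T and NK cell, macrophage and monocyte, dendritic cell, mast cell and basophil, stroma and endothelium, sort markers, interferon response, inflammatory cytokine and NF-kB response, immediate early and dissociation stress, cell cycle, cyclin-dependent kinase inhibitors and quiescence, Notch, Wnt and TGF-beta targets, MHC class II and antigen presentation, H2 region outside class II, and sex-linked. List members with no probe set of their own, such as the Sca1 gene, were not tested. The lists were tested between KSL and Lin+ cells with camera (preset correlation 0.01, and also an estimated correlation) and fry. With an estimated correlation camera has only the 2 residual degrees of freedom of the fit. A list that misses the threshold there need not be unshifted. For arthritic against control pools the median of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description. Members were also counted as above or below both controls, and tested with adjustment over the list alone.

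Named genes were the 12 highest and 12 lowest fold changes among genes past the threshold and of 1 direction in all 3 genotypes for KSL against Lin+ cells. For arthritic KSL cells they were the 12 furthest above and the 12 furthest below both controls by the difference to the nearer control, for arthritic Lin+ cells the 8 and 8, and for the interaction the 5 with the smallest p. Of each list the 2 to 4 members with the largest absolute value are named, and the sort marker, MHC class II and sex-linked lists served as label checks. Alternatives were quantile normalization, median centring, other filters, other handling of several probe sets, other floors, eBayes with trend and robust, no block, fits on 1 cell type, each genotype or control array left out, other fold and level minimums, and a random block for the genotype. Choosing the probe set on the other 5 arrays, fry on the arthritic comparison and an estimate of the block correlation from the control pools were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.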

Results

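Gene expression was measured on 6 arrays of mouse bone marrow cells, with 1 array per pool of mice and cell type. KSL cells carry Kit and Sca1 and lack the markers of mature lineages, and they are the part of the marrow that holds hematopoietic stem cells and early progenitors. Lin+ cells carry those lineage markers and were taken from the same mice. All mice were 6 to 7 weeks old, on a C57BL/6 background, and each pool held males and females. KRN mice carry a transgenic T cell receptor, and B6xG7 mice carry the MHC class II molecule I-Ag7 from the G7 strain. KRNxG7 mice carry both and were the arthritic group, with 7 to 9 mice. Each cell type therefore had 1 arthritic array and 2 control arrays of different genotype. The median intensity lay between 75.3 and 78.9 on the 6 arrays. Across probe sets, log2 intensities of arrays of the same cell type correlated at 0.983 to 0.993, and those of different cell types at 0.898 to 0.920. The number of arrays limits the precision of every value.

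Marker genes were read in each pool as a check of the labels. In the order B6xG7, KRN and KRNxG7, which is kept for all intensities, Kit was at 4566, 4398 and 3839 in KSL cells and at 439, 628 and 363 in Lin+ cells. The lineage marker Itgam was at 76.8, 134 and 130.3 in KSL cells and at 1111, 1627 and 1676 in Lin+ cells. The T cell receptor gene Trav9d-3, which was chosen after its values were seen, was 88.7-fold higher in the KSL pools with the KRN transgene than in the B6xG7 pool, at 78.7, 8291 and 5882. In Lin+ cells the ratio was 10.3. Among the other receptor genes read, Trbv1 had a KSL ratio of 5.77 and the rest 0.435 to 1.03. Whether the probe set of Trav9d-3 reads the transgene itself was not tested. Both sexes were seen in every pool. Xist, transcribed from the inactive X chromosome of females, was at 11770.4, 8494 and 9086 in KSL cells, and Eif2s3y, a gene of the Y chromosome, was at 746, 1545 and 1745. Eif2s3y was also lowest in the B6xG7 pool in Lin+ cells, at 996, 1670.2 and 1562.

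KSL cells were compared with Lin+ cells to learn whether the sorted KSL cells were primitive, the purpose given in the series text. Genes of stem cells were far higher in KSL cells in all 3 pools. Mecom, a transcription factor of long-term stem cells, was at least 126-fold higher, and Procr, a surface receptor of stem cells, at least 99.6-fold, with Lin+ values at or near the floor of the scale. Angpt1, a ligand of the Tek receptor, was 77.0-fold higher (log2 6.27 ± 0.19 SE, n = 3 pairs), Cd34, a progenitor surface protein, near the floor on 1 Lin+ array, was at least 79.9-fold higher (log2 6.32 ± 0.28), and Mycn, at the floor on 1 Lin+ array, was at least 48.7-fold higher. All 17 tested members of the stem cell list were higher in KSL cells past the threshold, with a median log2 difference of 3.94. The camera test gave an adjusted p = 5.95e-11, and adjusted p = 0.587 with an estimated correlation, where the test has only 2 residual degrees of freedom. Among other genes, Myct1, near the floor in Lin+ cells, was at least 100.4-fold, and Adgrl4, an adhesion receptor, 62.0-fold higher. Pdgfrb, Bex1 and Ociad2, near the floor on 1 or more Lin+ arrays, were at least 59.3-fold, 58.0-fold and 57.7-fold, and Ctla2a, with all KSL values over 10000, at least 42.5-fold higher. Bpifc was at least 71.3-fold higher, since it was at the floor on all Lin+ arrays. With the mean of all probe sets of a gene, Mycn was at log2 1.86 in place of 5.61 and Ociad2 at 3.69 in place of 5.85. Angpt1 ranged from log2 4.18 to 6.44 over the settings.

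Genes of neutrophils, macrophages, B cells and late erythroid cells were higher in Lin+ cells. Cd177, a neutrophil surface protein, was at least 539-fold higher in Lin+ than in KSL cells, Slfn4 at least 488-fold, Lrg1 at least 398-fold and Chil1 at least 265-fold, since their KSL values were at or near the floor. The matrix metalloproteinase Mmp8, also near the floor in KSL cells and over 10000 on 1 Lin+ array, was at least 200.2-fold higher (log2 -7.65 ± 0.22 SE, n = 3 pairs). Mmp9, the formyl peptide receptor Fpr2 and Ifitm6 were at least 220.3-fold, 209-fold and 175-fold higher, since all their Lin+ values were over 10000, where the scale can be compressed. Slfn1, Retnlb, Olfm4 and Ceacam10 were at the floor on all KSL arrays, and were at least 422-fold, 384-fold, 214-fold and 211-fold higher in Lin+ cells. With the mean of all probe sets of a gene, Slfn1 was at log2 -4.53 in place of -8.72 and Ceacam10 at -4.90 in place of -7.72. All 16 neutrophil genes (median log2 -6.44) and all 15 macrophage and monocyte genes (-3.40) were lower in KSL cells, as were 13 of 14 B cell genes (-3.95) and 6 of 8 late erythroid genes (-2.16). In camera these 4 lists had adjusted p = 3.29e-12, 9.37e-09, 3.70e-08 and 0.00231, and each had adjusted p = 0.587 with an estimated correlation. Several neutrophil genes, such as S100a8 at 22201, 22089.9 and 23852, were close to the top of the scale in Lin+ cells.

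**Figure D1:**
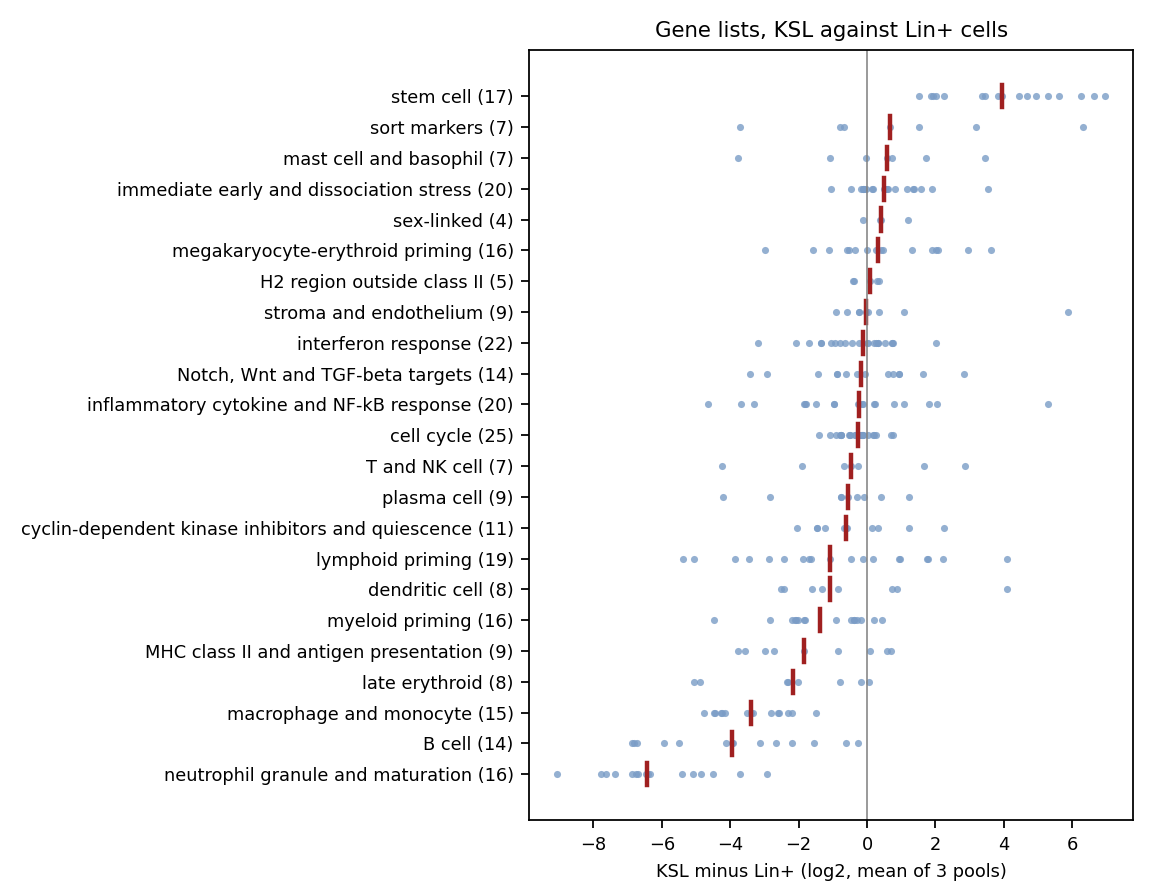
Difference between KSL and Lin+ cells for the tested members of 23 gene lists. The horizontal axis is the log2 difference as the mean over 3 pools. Each point is 1 gene, the red bar is the list's median, and the number of genes is in parentheses. All 17 stem cell genes lie above 0, and all 16 neutrophil genes and all 15 macrophage and monocyte genes lie below it.

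The other progenitor lists held members that went both ways. Of 16 myeloid priming genes, 1 was higher and 9 were lower in KSL cells, with the Fc receptor gene Fcgr3 at log2 -4.48 and Csf2ra at -2.85. Their median was -1.36, with adjusted p = 3.57e-04 in camera and adjusted p = 0.624 with an estimated correlation. Of 19 lymphoid priming genes, 6 were higher, among them the receptor gene Flt3 (4.11), and 11 were lower, among them the B lineage genes Igll1 (-5.38 or lower, at or near the floor in KSL cells) and Ebf1 (-5.07). The lymphoid median was -1.07, with adjusted p = 0.143. Of 16 megakaryocyte-erythroid priming genes, 6 were higher and 4 were lower (median 0.32), which did not pass camera (adjusted p = 0.561) but passed fry, which compares a list with no other genes (adjusted p = 0.0257). Vwf, which encodes a platelet adhesion protein, was at 3.63 and Itga2b at 2.96, while Rhd, a red cell antigen, was at -2.97. Of 9 genes of MHC class II and its antigen presentation, 1 was higher and 6 were lower (median -1.85), with H2-Eb1 at -3.79 and H2-Aa at -3.58. That list had adjusted p = 0.0371 in camera and adjusted p = 0.587 with an estimated correlation, and missed the threshold with no filter, with a stricter filter and with no block (adjusted p up to 0.0929). Of 25 cell cycle genes, 2 were higher and 10 lower (median -0.25), with Rrm2 at -1.41 and Ccne2 at -1.08. The cell cycle list passed narrowly, at adjusted p = 0.0498, and had adjusted p = 0.587 with an estimated correlation. It missed the threshold without any 1 of the 3 genotypes, with quantile normalization and with the mean of all probe sets (adjusted p up to 0.179).

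Response genes and markers of rarer cells gave smaller or mixed differences. Of 20 immediate early genes, 9 were higher in KSL cells and 2 were lower (median 0.51), with Nr4a1 at 3.54 and Egr1 at 1.89. An effect of the isolation, by flow cytometry for KSL and magnetic beads for Lin+ cells, cannot be told apart from the cell type here. Among 20 genes of the inflammatory cytokine and NF-kB response, 5 were higher and 9 lower (median -0.24), with the interleukin 1 receptor Il1r1 at 5.29 and its ligand Il1b at -4.66. Among 22 interferon response genes 3 were higher and 8 lower (-0.12), and among 11 cyclin-dependent kinase inhibitor and quiescence genes 2 were higher and 7 lower (-0.61), with the inhibitor Cdkn1c at 2.25 and Cdkn2d at -2.04. Of 14 Notch, Wnt and TGF-beta targets, 4 were higher and 6 lower (-0.18). Counts of higher and lower members were 2 and 5 of 9 for plasma cells (-0.55), 2 and 3 of 7 for T and NK cells (-0.47), and 2 and 5 of 8 for dendritic cells (-1.08). They were 4 and 2 of 7 for mast cells and basophils (0.60), 2 and 1 of 9 for stroma and endothelium (-0.03), and 4 and 3 of 7 for the sort markers (0.69). Of 5 genes of the H2 region outside class II, 0 passed, and of 4 sex-linked genes 1 was higher (0.40). None of the lists in this paragraph passed camera, at adjusted p from 0.143 upward. The fry test, which asks only whether a list's genes move on balance in one direction, passed for the immediate early (adjusted p = 0.0272), plasma cell (0.0257) and quiescence lists (0.0257). The median and the mean or fry direction differed in sign for the dendritic, stroma and H2 region lists (means of -0.38, 0.60 and -0.01, fry up, up and down). Over the settings the medians of the dendritic, interferon response, Notch, Wnt and TGF-beta target, stroma, sort marker and H2 region lists did not keep their sign.

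Over all 12348 genes tested, limma with the genotype as a block called 6421 genes at an adjusted p of 0.05, of which 3615 were higher and 2806 lower in KSL cells. At least a 2-fold difference was found for 1872 of the higher and 1495 of the lower genes. Of the 23 lists, 8 passed camera with the preset correlation, 0 passed with the correlation estimated from these arrays, and 12 passed fry. With an estimated correlation camera has 2 residual degrees of freedom, so the 0 does not show that correlation between genes explains the calls. The MHC class II list had an estimated correlation of -0.0701, under the preset 0.01, and still did not pass. Kit, Itgam and the other sorted markers differ by the sort itself. The cell type also coincides with the isolation method, flow cytometry for KSL and magnetic beads for Lin+ cells, so the 2 cannot be separated.

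The arthritic KSL pool was set against both control pools, the comparison named in the study's title. Neutrophil genes were among the highest above both controls. Chil3, a chitinase-like protein of myeloid cells, was at 58.8, 172 and 765, 4.46-fold above the nearer control, with no replicate of the arthritic pool. S100a9 and S100a8, which form calprotectin, were 2.97-fold and 2.38-fold above the nearer control, the granule genes Camp and Ngp 2.88-fold and 2.29-fold, and the protease inhibitor Slpi 2.23-fold. The ribonuclease gene Ear3 was 3.04-fold above it, the lipoxygenase gene Alox15 2.51-fold, the NADPH oxidase subunit Cybb 2.34-fold, Fn1, which encodes fibronectin, 2.34-fold, Cttnbp2nl 2.23-fold and the LIF receptor Lifr 2.21-fold. The 2 controls also differed for neutrophil genes. Camp was at 67.1, 209 and 602, S100a9 at 98.1, 232 and 689, and S100a8 at 279 and 673 in the controls. Camp in B6xG7 stood at log2 -1.64 from KRN, beside 1.52 for the arthritic pool from KRN. The controls were closer for Ear3, at 272, 231 and 828. On the low side, the nearer control was at least 5.54-fold above the arthritic pool for the potassium channel Kcnj3, which was near the floor there, 4.20-fold for Ifng, which encodes interferon gamma, 4.13-fold for Myl10, and, also near the floor there, at least 3.30-fold for the progesterone receptor Pgr and 2.43-fold for the amino acid transporter Slc38a5. It was 2.43-fold above for the guanylate-binding protein Gbp6, 2.40-fold for Des, 2.36-fold for the C5a receptor C5ar1, 2.33-fold for Nr1h3, and 2.28-fold for the erythroid membrane gene Ermap. For Gimap3 and Gimap4, GTPases of lymphocytes, it was 2.29-fold and 2.26-fold above. With the mean of all probe sets of a gene, log2 differences from the mean of the controls shrank from 1.29 to 0.64 for Fn1, 1.25 to 0.70 for Lifr, -1.49 to -0.76 for C5ar1 and -1.31 to -0.79 for Des.

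By gene list, megakaryocyte-erythroid and MHC class II genes stood lowest. Of 16 megakaryocyte-erythroid genes, 14 lay below both controls and 0 above, with a median log2 of -0.63, lower than all of 10000 random lists of matched expression (-0.76 against B6xG7 and -0.52 against KRN alone). Car1, an erythroid carbonic anhydrase, was at log2 -1.44 ± 0.31 SE, the erythroid transcription factor Klf1 at -1.33 ± 0.31, the platelet chemokine Pf4 at -1.16 ± 0.29 and Rhd at -0.90 ± 0.22. Adjusted over the list alone 5 of the 16 passed, and 0 passed over all genes. Of 9 genes of MHC class II and its antigen presentation, 7 lay below both controls (median -0.64), with H2-Eb1 at -1.45, H2-Ab1 at -1.10, Cd74 at -1.09 and H2-Aa at -1.07, and 2 passed adjusted over the list alone. H2-Aa was at 1581, 417 and 386 and was thus also low in the KRN pool. As a label check H2-Aa did not part the B6xG7 and KRNxG7 pools, which carry I-Ag7, from the KRN pool. Of 22 interferon response genes, 16 lay below both controls (median -0.23), with Iigp1 at -0.86. Of 16 neutrophil genes, 12 lay above both controls and 3 below (median 0.52, or 0.68 against B6xG7 and 0.51 against KRN alone), and 7 passed adjusted over the list alone. Chil3 was at 2.93 ± 0.57, Camp at 2.35 ± 0.61, S100a9 at 2.19 ± 0.48 and S100a8 at 1.89 ± 0.48. Of 16 myeloid priming genes, 11 lay above both controls and 0 below (median 0.26, or 0.46 against B6xG7 and 0.07 against KRN alone), with Ly86 at 0.83 and Cebpa, a myeloid transcription factor, at 0.72. The medians were 0.21 for macrophages and monocytes (0.12 against KRN alone and 0.00 to 0.64 over the settings), -0.25 for late erythroid genes (-0.38 to -0.15 over the settings), 0.16 for Notch, Wnt and TGF-beta targets, 0.51 for sex-linked genes (0.95 against B6xG7 and 0.09 against KRN alone) and -0.15 for the stem cell list. The cell cycle list had a median of -0.04.

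No single gene passed the test across all genes: limma called 0 of 12348 genes, with a smallest adjusted p = 0.143 for Kcnj3, and 363 genes had an unadjusted p under 0.05, against 617.4 by chance. At least 2-fold from both other pools, the arthritic KSL pool had 13 genes higher and 22 lower, the KRN pool 6 and 13, and the B6xG7 pool 14 and 25. Against KRN alone the arthritic pool had 40 and 39, and against B6xG7 alone 93 and 76. In the lowest or highest 2.5% of random lists were 10 of the 23 lists for the arthritic pool, but also 11 for KRN and 11 for B6xG7, where chance gives 1.15. Each control was set against a mean that holds the arthritic pool, so a shift of that pool also enters the counts of the controls. The B6xG7 pool stood on the other side of several lists, at 0.44 for megakaryocyte-erythroid and -0.61 for neutrophil genes. Those values are against a mean that holds the arthritic pool, and against KRN alone they were 0.12 and -0.31. With fry, 0 of 23 lists passed, with a smallest adjusted p = 0.821. The arthritic pool is 1 array and its own genotype, so arthritis and genotype cannot be separated. On single controls, the stem cell median was 0.03 against KRN and -0.33 against B6xG7, and that of Notch, Wnt and TGF-beta targets was -0.02 against B6xG7.

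**Figure D2:**
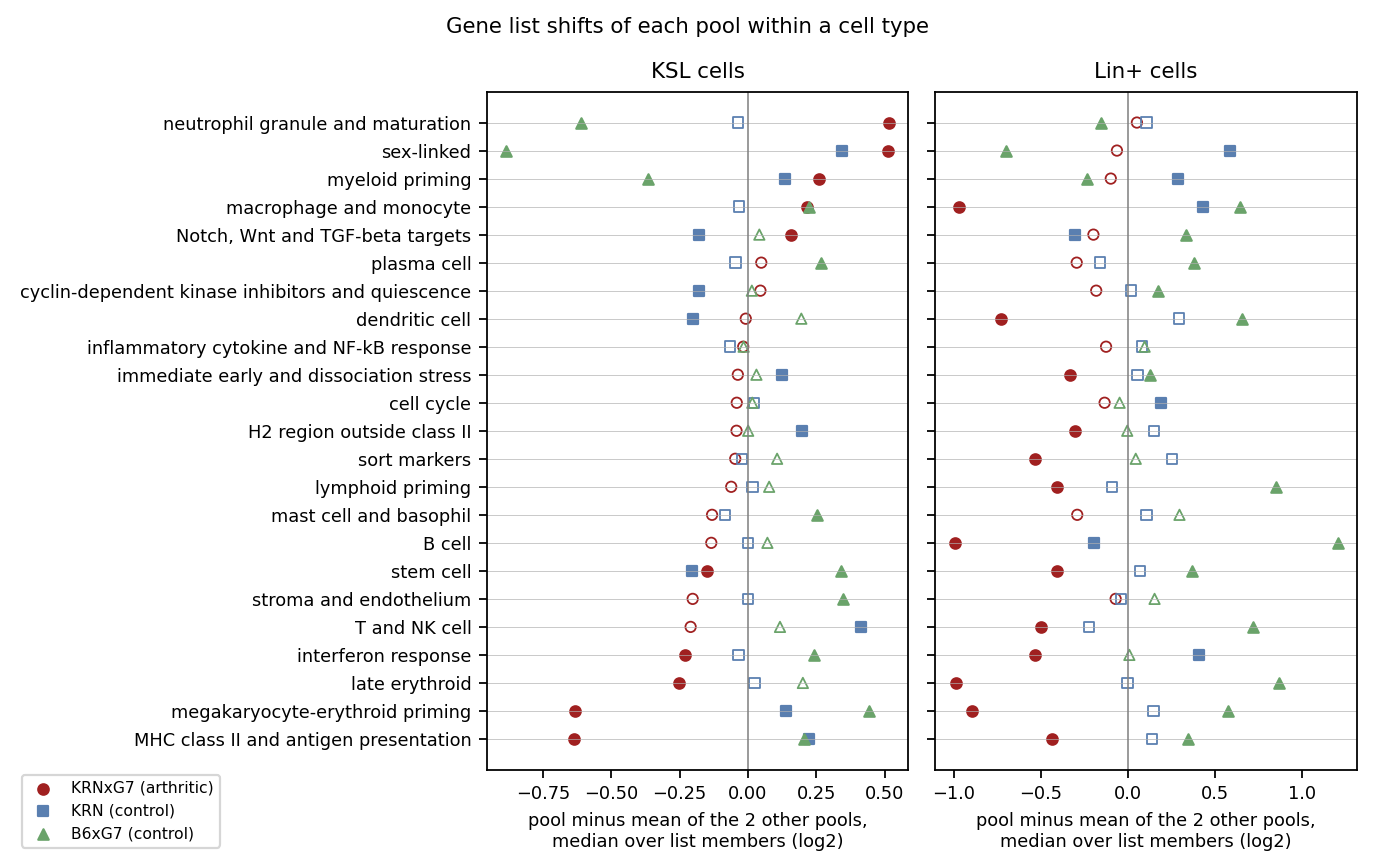
Median shift of 23 gene lists for each pool against the mean of the 2 other pools, in KSL cells (left) and Lin+ cells (right). The horizontal axis is in log2 units, with 1 point per pool, and filled points lie in the lowest or highest 2.5% of 10000 matched random lists. In KSL cells the arthritic pool is lowest for megakaryocyte-erythroid (-0.63) and MHC class II genes (-0.64) and highest for neutrophil genes (0.52).

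The arthritic Lin+ pool was compared with its controls in the same way. Genes of B cells, macrophages and red cell precursors were low in it. Lin+ cells are a mixture, so fewer cells of a kind cannot be told apart from lower expression in them. Of 14 B cell genes 12 lay below both controls and 0 above (median log2 -0.995, or -1.44 against B6xG7 and -0.53 against KRN alone), with Fcmr, an IgM receptor, at -1.74 ± 0.33 SE, Fcer2a at -1.69 ± 0.58 and the complement receptor Cr2 at -1.51 ± 0.33. Adjusted over the list alone, 3 of the 14 passed. All 8 late erythroid genes lay below both controls (median -0.99, or -1.30 against B6xG7 and -0.48 against KRN alone), with 3 passing adjusted over the list alone and Alas2, the erythroid enzyme of the first step of heme synthesis, passing over all genes. Of 16 megakaryocyte-erythroid genes 11 lay below both controls (median -0.89), with Klf1 at -1.51 and Gfi1b at -1.37, and 9 passed adjusted over the list alone. Of 15 macrophage and monocyte genes 10 lay below both controls and 2 above (median -0.97), with 7 passing adjusted over the list alone. Cd5l, Axl and the complement genes C1qa and C1qc, all genes of tissue macrophages, were at -2.06, -1.94, -1.98 and -1.76.

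Of 22 interferon response genes in Lin+ cells, 19 lay below both controls (median -0.53, or -0.28 against B6xG7 and -0.71 against KRN alone), with Iigp1 at -1.38 and Gbp2 at -1.16. The dendritic cell list had a median of -0.73, with Ccr7 at -2.14 and Siglech at -1.83, and 4 of its 8 genes passed adjusted over the list alone. The medians were -0.44 for MHC class II, -0.50 for T and NK cell, -0.41 for lymphoid priming, -0.33 for immediate early and -0.30 for other H2 region genes. They were -0.41 for the stem cell list and -0.53 for the sort markers. Single controls moved 4 of these medians by over 1.5 times, to -0.93 against B6xG7 and -0.18 against KRN for T and NK cell, -0.83 and -0.22 for lymphoid priming, -0.17 and -0.13 for other H2 region genes, and -0.27 and -0.30 for the sort markers. Neutrophil genes, at 0.05 (0.10 against B6xG7 and -0.00165 against KRN alone), and myeloid priming genes, at -0.10 (0.08 and -0.25), were not in the lowest or highest 2.5% of random lists, but many neutrophil genes were close to the top of the scale in Lin+ cells, where a change can be hidden. With fry, 0 of 23 lists passed (smallest adjusted p = 0.0945). For the arthritic pool 13 lists were in the lowest or highest 2.5% of random lists, all low, while 7 were for KRN and 16 for B6xG7. The B6xG7 pool stood apart in the other direction, with a B cell median of 1.20 and a late erythroid median of 0.87. Those medians are against a mean that holds the arthritic pool, and against KRN alone they were 0.88 and 0.41. A shift of the arthritic pool thus also enters the counts of lists for the controls. With genes filtered at the 60th percentile of mean intensity the macrophage and monocyte median turned to 0.09, a filter that leaves out C1qa, Cd5l, Axl and other members of low mean intensity.

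Single genes in Lin+ cells included 11 that passed limma over all 12348 genes, with 1622 at an unadjusted p under 0.05. The 8 that rose were Grik5, a glutamate receptor subunit (log2 3.24 ± 0.24 SE, adjusted p = 0.0403), Plekhg2 (2.85), the zinc finger gene Zfp692 (2.79), Wnt1 (2.78), Kcnj3 (2.59), Scrn3 (2.40), Pfdn6 (2.31) and Mtx1 (2.16). The 3 that fell were Traf3ip2, an adaptor of the interleukin 17 receptor (-3.04 ± 0.23 or lower, adjusted p = 0.0403), Guca1b (-2.32 or lower), both with arthritic values near the floor, and Alas2 (-2.01). Scrn3, Pfdn6 and Mtx1 fell outside the rule for named genes and were chosen after their values were seen. Of the others furthest from both controls, Ccdc173, near the floor in both controls, was at least 8.12-fold, Farsa, a tRNA synthetase subunit, 5.79-fold and Cox6a2 5.46-fold above the nearer control. With the mean of all probe sets of a gene, the log2 differences were 0.49 for Ccdc173 in place of 3.54, 0.85 for Farsa in place of 2.90 and 0.91 for Cox6a2 in place of 2.76, and -1.45 for Clcf1 in place of -2.63 and -1.11 for Guca1b in place of -2.32. The nearer control was at least 4.48-fold above the arthritic pool for the cytokine Clcf1, which was near the floor there, 4.41-fold for the ficolin gene Fcna, 4.11-fold for the noncoding RNA Ftx, 3.89-fold for Cd200 and 3.88-fold for C1qa. At least 2-fold from both other pools, the arthritic Lin+ pool had 71 genes higher and 119 lower, KRN 15 and 58, and B6xG7 83 and 16. Against KRN alone the arthritic pool had 223 and 257, and against B6xG7 alone 130 and 392. Of the 71 higher genes 21 had other probe sets at or above the median level, and these 36 had a median of 0.03 against 1.45 for the counted ones of the same genes, with 5 at 2-fold or more. Other probe sets did not follow for Cox6a2 (-0.56), Farsa (-0.06 to 0.25), Mtx1 (-0.26) and Scrn3 (-0.74 and -0.02), nor for Guca1b, where the arthritic pool lay between the controls. The count of 11 became 0 with no filter on low genes and with all probe sets counted separately. The calls were also lost without any 1 of the 4 control arrays and in a fit on the Lin+ arrays alone. Those fits have fewer residual degrees of freedom, so they do not show that the calls depend on an array.

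**Figure D3:**
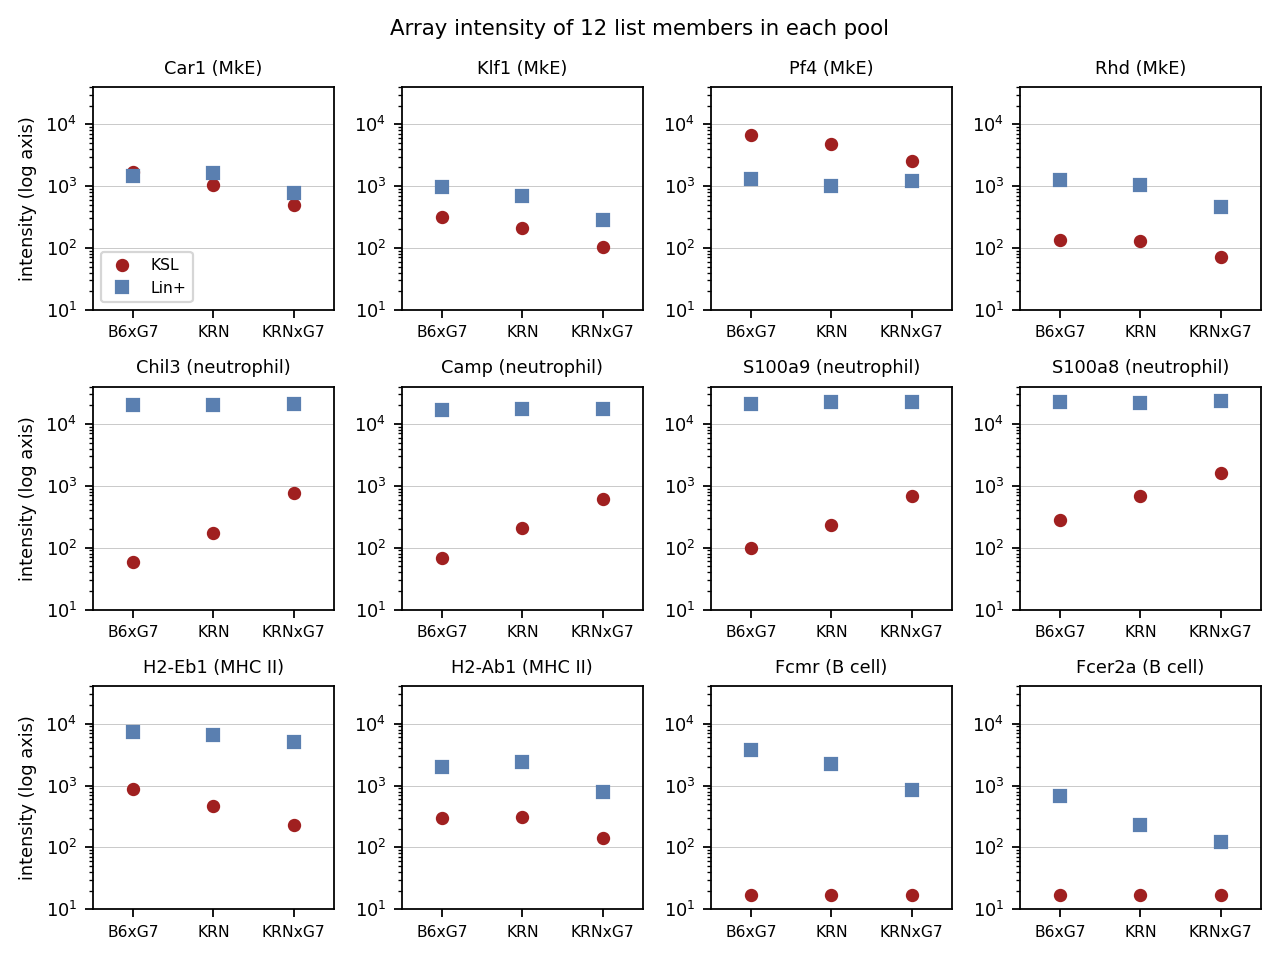
Intensity of 12 list members in each pool, on a log axis, with 1 array per point, circles for KSL and squares for Lin+ cells. MkE marks megakaryocyte-erythroid genes, and KRNxG7 is the arthritic pool. Chil3 in KSL cells is at 58.8, 172 and 765, and Klf1 in KSL cells at 310.3, 213 and 102.

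The difference between arthritic and control pools was also compared between KSL and Lin+ cells. Kcnj3 was the 1 gene past the threshold, at log2 -5.08 or lower, with its arthritic KSL value near the floor (adjusted p = 0.0158), with 795 genes at an unadjusted p under 0.05. Its intensity was 127, 124 and 22.4 in KSL cells and 133, 127 and 785 in Lin+ cells. Next by p came Traf3ip2 at 3.25 or higher, Zfp692 at -3.06, Grik5 at -3.13 and Scrn3 at -2.79, which did not pass. Over the settings Scrn3 ranged from -2.92 to -0.63. The 3 other probe sets of Kcnj3 were at or near the floor on all arrays. Its call was lost with no filter on low genes and with a floor at the 40th percentile. It was also lost without any 1 of the 4 control arrays, where fewer residual degrees of freedom remain. With the filter at the 60th percentile, the mean of all probe sets or all probe sets counted separately, 0 passed for the interaction. Genes at least 2-fold from both controls in the same direction in both cell types were Cttnbp2nl, higher, and Slc38a5, Guca1b, Gbp6, Ermap, H2-Ab1 and Klf1, lower, with Guca1b not so on its other probe set. The same counts were 1 higher and 4 lower for the KRN pool, and 0 and 1 for B6xG7. By list, 10 of 16 megakaryocyte-erythroid, 14 of 22 interferon response and 6 of 9 MHC class II genes lay below both controls in both cell types. So did 5 of 8 late erythroid, 3 of 5 other H2 region and 6 of 14 B cell genes. Of 16 neutrophil genes, 7 lay above both controls in both cell types and 1 below. The share over all genes was not counted. These counts use the sign alone. In Lin+ cells the neutrophil median was 0.05. There S100a9, Camp and Chil3 were close to the top of the scale and only log2 0.000243, 0.0305 and 0.0850 above the nearer control. Over all genes the arthritic Lin+ array ran slightly lower, by a median log2 of -0.0648 against B6xG7 and -0.0883 against KRN.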

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

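For the patterns weighed here, the tests with other probe sets of the same genes, with the probe set chosen on the other 5 arrays, with the sex composition and with the strain difference were chosen after the result was seen, as was fry on the arthritic lists.

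The potassium channel gene Kcnj3 differed between cell types in its response, by log2 -5.08 or lower in the test of the difference itself. That call was lost with no filter on low genes and with a floor at the 40th percentile. It was also lost without any 1 of the 4 control arrays, where fewer residual degrees of freedom remain. The interaction also gave 0 with the filter at the 60th percentile, the mean of all probe sets or all probe sets counted separately. The arthritic KSL value of Kcnj3 lay near the floor, and its other probe sets were at or near the floor. The macrophage and monocyte list had medians of opposite sign, 0.21 in arthritic KSL cells (0.00 to 0.64 over the settings) and -0.97 in arthritic Lin+ cells (-1.07 to 0.09). For that list the test of the difference (fry on the interaction) gave an adjusted p = 0.278, so a difference between the cell types is not established.

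In arthritic Lin+ cells 71 genes were at least 2-fold above both controls, and 67 with each probe set chosen on the other 5 arrays, which argues against the choice of the brightest probe set as the source. The 36 other probe sets of 21 of these genes, at or above the median level, had a median of only 0.0271 on the log2 scale (95% interval over resampled genes -0.0366 to 0.285), against 1.45 for the counted probe sets. For the 119 genes below both controls, 32 other probe sets had a median of -0.83 against -1.21. Signal of single probe sets rather than of the genes' mRNA is a candidate explanation for part of these rises, but not for Vcan, Ednrb and Prune2, chosen after their values were seen, for which 5 other probe sets were also at least 2-fold higher. It stays open for genes such as Grik5 and Plekhg2, which had no other probe set to compare.

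Megakaryocyte-erythroid genes stood lower in arthritic KSL cells, with a median of -0.63. With quantile normalization the median was -0.69, which argues against the scaling of the arrays. The KSL arrays already had near-equal median intensities of 78.9, 78.2 and 77.9, so this test had little to change. The list's step from KRN to KRNxG7 was 4.39 times its step from B6xG7 to KRN (95% interval over resampled members 1.05 to 6.98), while this ratio was 0.0832 for genes of the Y chromosome, which argues against the sex composition of the pools as the whole source. The B6xG7 pool stood at 0.44 from the mean of the 2 other pools, but that mean holds the arthritic pool. Against KRN alone, the only difference without arthritis, B6xG7 stood at 0.12, beside -0.52 for the arthritic pool against KRN. A strain difference still cannot be told apart from arthritis, since each genotype is 1 pool. An effect of arthritis, or of the KRNxG7 genotype, may underlie the pattern and stays untested.

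Neutrophil genes stood higher in arthritic KSL cells, with a median of 0.52, and RNA or cells of mature neutrophils carried over into the sort could raise genes far higher in Lin+ cells by a common share of their Lin+ level. Over 75 such genes below the top of the scale the median share was 0.128% (95% interval 0 to 0.254), with 45 of 75 above 0, and over 17 genes at the top of the scale it was 0.599% (0.163 to 1.72). The rises of Chil3, Camp, S100a9, S100a8 and Ngp would need 2.30% to 5.05%, while the 11 other genes of the list had -3.11% to 1.49%, with Cd177, Mmp9, Cxcr2 and Mmp8 at 0.0772%, 0.163%, 0.220% and -0.0871%, which argues against 1 common share of the levels as measured. Carry-over stays open where the Lin+ values of those 5 genes, 17734 to 23852, are compressed far more than that of Mmp9, at 20052. These arrays cannot show this. It also stays open for carried-over cells of a make-up unlike the Lin+ pool, since the share assumes that pool's make-up. The lineage-negative gate was meant to remove such cells, and expression by the KSL cells themselves stays open. A difference between strains was not tested for this list and stays open too. Without arthritis, the KRN pool stood at a median of 0.31 against B6xG7, beside 0.51 for the arthritic pool against KRN.

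For KSL against Lin+ cells, 3 against 3 arrays make 10 splits, and 1 split, the real one, gave as many genes (6791 without the block, highest other 0). Among the 4 splits that part all 3 pairs, again only 1 gave as many (6421, highest other 0). Neither number of splits allows a share under 0.05.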

How the results depend on the processing

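Results added after the data were seen are those with the probe set chosen on the other 5 arrays, fry on the arthritic lists and the random block. The planned estimate of that block's correlation could not be had with 2 residual degrees of freedom, so the correlation of the control pools (-0.0651) was used. The count of 0 in arthritic KSL cells held in all 16 settings, the reported one included. All 24 named genes of KSL against Lin+ cells kept direction and call. None of the other named genes reversed, but 32 of 328 values in KSL and 21 of 217 in Lin+ cells moved. The call of Kcnj3 for the interaction was lost in 6 of the 12 settings that gave it a value, the reported one included. For list medians, 47 of 276 in KSL and 36 of 276 in Lin+ cells moved by more than the spread, and 8 calls of lists were lost and 1 gained of 253. Values near the floor limit genes of low intensity.

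Counted separately, probe sets gave 13159 calls between KSL and Lin+ cells (7601 higher, 5558 lower), 0 in arthritic Lin+ cells and 0 for the interaction, and 30 higher in KSL and 152 higher and 266 lower in Lin+ cells by 2-fold. With the mean of all probe sets, 7 genes passed in Lin+ cells and 0 for the interaction, with 11 lower in KSL and 44 higher in Lin+ cells. With no filter both tests gave 0. With the filter at the 60th percentile the interaction gave 0, Lin+ cells 46 higher and 75 lower, and the Lin+ macrophage list 0.0892. A floor at the 40th percentile gave 22 in Lin+ cells and 0 for the interaction, trend and robust gave 21, and the Lin+ arrays alone gave 0. An estimated correlation, with 2 residual degrees of freedom in camera, left 0 lists past the threshold. At 1.5-fold the counts were 75 and 93 in KSL and 257 and 569 in Lin+ cells, and at 3-fold 2 and 4, and 29 and 21. With no level minimum 37 were lower in KSL cells, and at the 75th percentile 7 and 8 in KSL and 46 and 32 in Lin+ cells. Without each control array of the cell type, which leaves 1 control to compare with, the 2-fold counts ranged from 40 to 93 higher and 39 to 76 lower in KSL cells. In Lin+ cells they ranged from 130 to 223 higher and 257 to 392 lower. The test calls in Lin+ cells and for the interaction were lost there, in fits with fewer residual degrees of freedom. Without KSL control replicate 1 and 2 the KSL stem cell median was 0.0281 and -0.33, and that of Notch, Wnt and TGF-beta targets was 0.25 and -0.0170. The filters and the left-out arrays change which genes or pools are compared, and otherwise the cause was not tested.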

Other observations

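The comparison with correlations between different pools, below, was added after the value of that test had been seen, and the genes of the KRN pool were chosen after their values were seen.

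Regulators of the cytokine response went both ways in arthritic KSL cells, for which the list median was -0.02 (0.15 against KRN alone). Socs3, a feedback inhibitor of cytokine signalling, was at log2 1.26 ± 0.41 SE, and the C/EBP transcription factors Cebpd and Cebpb were at 0.98 and 0.91, while Tnfaip3, an inhibitor of NF-kB signalling, was at -0.90. None of them passed. In arthritic Lin+ cells the acute phase gene Saa3 was at 2.07 ± 0.24, and Ptgs2 and Il1b, which encode cyclooxygenase 2 and interleukin 1 beta, were at -2.04 and -1.50, though on another probe set of Ptgs2 the arthritic pool lay between the controls. Adjusted over the list alone, 3 of the 20 genes passed in Lin+ cells and 0 in KSL cells. The cell cycle inhibitor Cdkn1a was at 0.86 in KSL and 1.51 in Lin+ cells, and the heat shock gene Hspa1a at 1.13 in KSL cells.

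The KRN pool stood at least 2-fold from both other pools in both cell types for 5 genes. In the order B6xG7, KRN and KRNxG7, the intensity of Spata5l1 was 612, 66.1 and 427 in KSL and 663, 17.7 and 221 in Lin+ cells. Apobec3, a restriction factor of retroviruses, was at 2951, 971 and 1947 in KSL and at 2218, 475 and 1122 in Lin+ cells. Gba2 and Wdfy1 were also low, and the T cell receptor gene Trbv1 was high, at 55.6, 615 and 167 in KSL cells.

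A hypothesis was that the arthritic pool differs from its controls in the same genes in KSL and in Lin+ cells. Across 12348 genes, which are not independent replicates, its differences in both cell types correlated at 0.193, against -0.0332 for KRN and 0.0452 for B6xG7, which by the rule set beforehand would have favoured the hypothesis. Between different pools the correlations ranged from -0.234 to 0.218. Each pool was set against the mean of the others of its cell type, so a shift of the arthritic pool also enters these values. They are therefore not a background free of such a shift, and cannot show whether 0.193 lies within or beyond chance. Whether the change is shared stays open.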
